A study of Homo sapiens with 12 samples.

How the data were processed

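Gene expression was measured by RNA sequencing in 12 libraries from 3 human multiple myeloma lines (AMO1, H929, KMS20), control or ID2-OE, with 2 libraries per group. Per the labels, total RNA was extracted with the RNeasy mini plus kit, ribosomal RNA was depleted with the KAPA RNA HyperPrep RiboErase kit, and cells grew in RPMI-1640 with serum. The authors deposited whole-number read counts per gene symbol, 1 column per library, from reads aligned with STAR to hg38. The counter, strand setting, annotation, read length and any filter were not given in the sources used here. The deposited counts were not scaled between libraries. All 12 columns matched a library of the labels, none was left out, and groups were taken from the labels. The file held 28008 gene symbols; 25622 matched GENCODE 29, which gave loci, GC content and transcript length.

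Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept with filterByExpr over the 6 groups (15185 genes), scaled with TMM, and fitted with estimateDisp and glmQLFit as 6 group means over all 12 libraries. With 2 libraries per arm, the groups share 1 estimate of the spread. Contrasts were ID2-OE against control in each line, the average of the 3 lines, and the line differences together (F test); glmQLFTest p-values were two-sided and adjusted by Benjamini-Hochberg, and a gene was called at an adjusted p under 0.05. Standard errors of log2 fold changes were taken as the absolute change over the square root of F, which is approximate. CPM used TMM-scaled totals. Where an arm had 0 counts, the fold is a lower bound against 3 counts over the group, with the other arm's count taken as exact. With 1 to 3 counts in an arm the fold is the ratio of counts with a 95% exact counting interval. A list's median is also given with such members at their bounds where it differs.

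The 26 gene lists were written from general knowledge before the data were examined, as were the tests, the alternatives and the rule for naming genes, except where said. Of these, 24 had 5 or more tested members; ID2 was left out of each list it is in. Lists were tested with camera (limma 3.58.1, preset correlation 0.01), with camera at an estimated correlation, and with fry. The lists share members, and fry compares a list with no other genes. Named genes were a fixed panel of 16 genes, the 8 largest rises and 8 largest falls among called genes with a mean log2 CPM of at least 2, a named gene and no overlap between the arms, and 2 to 4 members of each list with the smallest p. For line differences the 8 smallest adjusted p-values were named. Because several of these genes were near 0 counts in an arm, the largest changes with 4 CPM or more in an arm of each line compared were added after seeing the data. Between-line overlaps were set against the number independent lists would share.

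The fit was tested on simulated data with 200 changed genes. The simulation drew genes independently and gave all 6 groups the same spread for a gene. Far more genes were called in the real data, so the rates below need not hold there. With changes in AMO1 alone it recovered 92.5% of genes changed by a log2 of 1 and 26.9% of those changed by 0.5, and 3.36% of its calls were false; KMS20 alone recovered 16.4% at 0.5. With changes in all 3 lines the average recovered 88.1% of those changed by 0.5, and 6.21% of the AMO1 calls were false. For changes in 1 line the interaction test recovered 59.7 to 73.1% at 1 and 5.97 to 7.46% at 0.5. Totals of 1.15e+07 to 4.15e+07 counts per library set the precision of the levels. Libraries of a group were not copies of each other (chi-square per degree of freedom 8.32 to 51.1, Spearman correlation 0.988 to 0.996).

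Alternatives were DESeq2 1.42.0 and its size factors, limma-voom, library totals alone, no filter, a stricter filter (1 CPM in all libraries of a group), glmTreat against a fold change of 1.5, an additive model, a replicate block, fits of each line alone, and leaving out each library. Added after seeing the data were thinning to the smallest total (3 draws), a trend in GC content and transcript length taken out (known for 95.3% of tested genes), and the 4 CPM minimum. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. Mitochondrially encoded genes, absent from the file, and immunoglobulin constant genes, with 1 of 15 in the file, were not tested. A few results for single genes that the naming rule picks are not reported here.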

Results

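RNA was sequenced from 3 human multiple myeloma lines, AMO1, H929 and KMS20, each as control cells and as a derivative that overexpressed ID2 (ID2-OE). Multiple myeloma is a cancer of plasma cells, the antibody-secreting end stage of B cells. ID2 is a helix-loop-helix protein without a DNA-binding basic region, which pairs with E proteins such as TCF3, TCF4 and TCF12 and keeps them from DNA. Both arms received doxycycline (0.25 µg/ml, 24 h). Each of the 6 groups had 2 libraries, 12 in all. The labels do not say whether the libraries of a group came from separate cultures, so the p-values measure only the spread between these samples, which may be technical. Total counts per library ran from 1.15e+07 in KMS20 ID2-OE to 4.15e+07 in the H929 controls. The most abundant gene of each library was the structural RNA gene RN7SL1 or RN7SK, with 2.81 to 5.93% of its counts. Of the genes in the file 15185 had enough counts to be tested, and the typical spread between libraries of a group (biological coefficient of variation) was 0.126. Levels are given in CPM (a gene's counts per 1e+06 of the library's scaled total) as mean ± SD with n = 2 libraries, and changes as ID2-OE over control. Intervals for genes near 0 counts cover counting error only. Lower bounds, given as at least a fold, cover it for the arm with 0 counts and take the other arm's count as exact. Where that count is small, the true fold may lie below the bound.

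The first comparison asked how much ID2, related ID genes and E protein genes each line expressed before overexpression. All 3 control lines expressed ID2 at a low level and TCF3 at a high one. TCF3 (chromosome 19, 1609290 to 1652605, hg38) stood at 255 ± 0.977, 449.9 ± 58.7 and 315 ± 24.0 CPM in AMO1, H929 and KMS20 (adjusted p = 3.23e-05 over the list alone, F test of the 3 control groups). ID2 (chromosome 2, 8678845 to 8684453) stood at 19.5 ± 6.91, 31.4 ± 3.69 and 39.5 ± 5.58 CPM (adjusted p = 0.000545). TCF4 was the most uneven E protein gene, at 180.5 ± 22.9, 29.1 ± 7.24 and 368 ± 38.3 CPM (adjusted p = 5.37e-11). ID3 ranged from 1.74 CPM in KMS20 to 71.7 CPM in H929 (adjusted p = 1.44e-10), and ID1 from 7.13 CPM in AMO1 to 27.5 CPM in H929 (adjusted p = 6.88e-06). LYL1 lay at 3.22 CPM or lower in each line (adjusted p = 4.82e-08). A difference in TCF12 was not detected (adjusted p = 0.438), with 76.7 ± 4.47, 67.8 ± 8.03 and 73.6 ± 2.78 CPM. Of the 7 genes, 6 differed between the control lines, both over the list alone and over all genes.

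The second comparison asked what ID2 overexpression changed in AMO1. MYC, XBP1, ID1 and ID3 fell and TCF4 rose in ID2-OE AMO1 cells. The DNA replication and mitosis lists were lower (39 of 40 and 35 of 35 genes fell) and the interferon list higher (16 of 28 rose, 1 fell) with camera's preset correlation, though none of the 3 passed with an estimated one (adjusted p = 0.168 each). In all, 4064 of 15185 genes were called (2261 rose, 1803 fell), 1534 of them by 2-fold or more; without control 2, 1598 rose and 1813 fell. Without control 1 or ID2-OE library 2 the number called was 2530 or 2428. ID2 rose from 19.5 ± 6.91 to 1582 ± 236 CPM, a log2 fold change of 6.32 (SE 0.23, adjusted p = 2.81e-10). The counts do not separate reads of the transgene from reads of the endogenous gene. ID1 and ID3 fell, by 2.82 and 2.87 on the log2 scale (adjusted p = 3.76e-05 and 8.67e-06), and TCF4 rose by 1.21 (SE 0.16, adjusted p = 0.000108). TCF3 stayed at 255 and 267 CPM, a change of 0.07 (SE 0.12, adjusted p = 0.744) that did not pass, nor did TCF12 (0.26, adjusted p = 0.186). MYC (chromosome 8, 127735434 to 127741434) fell from 933 ± 111 to 437 ± 31.7 CPM (-1.10 (SE 0.17, adjusted p = 0.000289)), and XBP1 (chromosome 22, 28794555 to 28800597), a plasma cell regulator, fell from 96.0 ± 3.39 to 53.5 ± 1.52 CPM (-0.84 (SE 0.12, adjusted p = 0.000155)). The proliferation genes MKI67 and E2F1 fell by 1.04 and 0.86 (adjusted p = 0.00446 and 0.00584), though without ID2-OE library 2 the adjusted p of E2F1 was 0.0716. IRF4 fell (-0.59 (SE 0.17, adjusted p = 0.0172)), but not without ID2-OE library 1 (0.0854) or 2 (0.0563). PRDM1 rose (0.37 (SE 0.11, adjusted p = 0.0234)); in 8 of the 12 fits without 1 library, those without any AMO1 or KMS20 library, its adjusted p was 0.0558 to 0.165. CCND1, CCND2 (chromosome 12, 4273772 to 4305350), CCND3 and CDKN1A did not pass (adjusted p = 0.932, 0.247, 0.0650 and 0.204). CDKN1A passed without ID2-OE library 1 (0.0316), and CCND3 without control 1 (0.0384) or either H929 control (0.0330 and 0.0326).

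The largest rises in AMO1 beside ID2 included genes absent from the AMO1 controls. MMP9 rose from 0 counts to 2.10 CPM, at least 28.4-fold, with the bound set by 3 counts over the group. TBX18, GLB1L2, MTUS1, APP and SYNM also rose from 0 counts, at least 6.35-, 4.23-, 4.23-, 3.02- and 2.72-fold, to levels of 0.186 to 0.467 CPM. Without AMO1 control 1 their adjusted p was 0.125, 0.0711, 0.0541, 0.104 and 0.149; that of TBX18 was 0.0631 without ID2-OE library 1 and that of SYNM 0.138 without library 2. Among genes with 4 CPM or more in an arm, a minimum chosen after seeing the data, the largest rises were EPSTI1, GBP2, SATB1, PTPRF, KRT86, COL22A1 and MX1. SATB1, a chromatin organizer, rose from 0.434 to 6.48 CPM (3.83 (SE 0.34, adjusted p = 3.00e-06)), and the interferon-induced genes MX1 and GBP2 from 1.23 to 14.9 CPM and from 0.361 to 7.29 CPM. EPSTI1 rose from 0.108 to 5.06 CPM (log2 fold change 5.08), with all of its control counts in control 1. The largest falls were DHRS2 (from 21.8 to 1.58 CPM), ARHGAP9 (from 13.9 to 1.73 CPM), ID3, ID1 and ST3GAL6 (from 2.76 to 0.452 CPM), with CGREF1, SULF2 and SCN2A near 0 counts. CGREF1 fell at least 3.31-fold to 0 counts, with an adjusted p of 0.0583, 0.0584 and 0.0825 without control 1 and ID2-OE libraries 1 and 2. SULF2 stood 9.93 times (95% counting interval 3.05 to 51.1) higher in the controls. SCN2A, at 0.181 CPM in the controls, was lost in 8 of 12 fits without 1 library (adjusted p 0.0551 to 0.285), those without any AMO1 library, either H929 ID2-OE library or either KMS20 control. With the 4 CPM minimum INHBE, AMPD1, MAGEC1 and DNMT3B joined the falls, DNMT3B from 79.9 to 19.4 CPM (-2.04 (SE 0.16, adjusted p = 1.18e-06)).

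Gene lists fixed before the data were examined put these changes in groups. In AMO1, 13 of 24 lists passed with camera at its preset correlation (5 higher, 8 lower), and none of the 24 with an estimated correlation. At an unadjusted p under 0.05 the estimated correlation gave 6 lists, and fry, which asks whether a list's genes moved one way on balance, gave 16 adjusted calls. Of 40 G1/S and DNA replication genes, 39 fell and 1 did not pass (the same adjusted over the list alone), with log2 fold changes such as CDC6 (-1.36) and E2F2 (-1.33). The G1/S median was -1.04 (adjusted p = 2.17e-30, with an estimated correlation adjusted p = 0.168). Of 35 G2/M and mitosis genes, 35 fell (the same adjusted over the list alone), with log2 fold changes such as CENPA (-1.84) and BIRC5 (-1.35). The G2/M median was -1.35 (adjusted p = 7.99e-31, with an estimated correlation adjusted p = 0.168). Of 43 replication-dependent histone genes, 40 fell and 3 did not pass (adjusted over the list alone, 42 fell), with log2 fold changes such as HIST1H2AC (-1.27) and HIST1H4C (-1.20). The histone median was -1.21 (adjusted p = 1.88e-22, with an estimated correlation adjusted p = 0.225). Of 30 MYC targets, 24 fell and 6 did not pass (adjusted over the list alone, 26 fell), with log2 fold changes such as ODC1 (-0.93), PA2G4 (-0.89) and TFRC (-0.93). The MYC target median was -0.59 (adjusted p = 1.70e-13, with an estimated correlation adjusted p = 0.168). Of 23 cholesterol synthesis genes, 14 fell and 9 did not pass (adjusted over the list alone, 16 fell), with log2 fold changes such as EBP (-0.84) and CYP51A1 (-0.98). The cholesterol median was -0.65 (adjusted p = 1.98e-06, with an estimated correlation adjusted p = 0.275). Of 26 unfolded protein and ER stress genes, 13 fell and 13 did not pass (adjusted over the list alone, 15 fell), with log2 fold changes such as CHAC1 (-1.45) and ATF4 (-0.58). The ER stress median was -0.48 (adjusted p = 3.19e-06, with an estimated correlation adjusted p = 0.225). Of 23 plasma cell genes, 2 rose, 11 fell and 10 did not pass (adjusted over the list alone, 3 rose and 12 fell), with log2 fold changes such as TNFRSF13B (-1.62), SLAMF7 (-1.32) and DERL3 (-1.73). The plasma cell median was -0.38 (adjusted p = 2.69e-05, with an estimated correlation adjusted p = 0.190). Of 19 immediate early genes, 3 fell and 16 did not pass (the same adjusted over the list alone), with log2 fold changes such as EGR1 (-1.76). The immediate early median was -0.34, or -0.44 with low-count members at their bounds (adjusted p = 0.00572, with an estimated correlation adjusted p = 0.423).

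A further 5 lists were higher in AMO1 with camera's preset correlation. Of 28 interferon-response genes, 16 rose, 1 fell and 11 did not pass (adjusted over the list alone, 17 rose and 1 fell), with log2 fold changes such as MX1 (3.62), OAS2 (1.54) and IFI6 (2.27). The interferon median was 1.31, or 1.43 with low-count members at their bounds (adjusted p = 1.09e-10, with an estimated correlation adjusted p = 0.168). Of 23 B cell genes, 9 rose, 1 fell and 13 did not pass (adjusted over the list alone, 10 rose and 1 fell), with log2 fold changes such as SPIB (1.16), BTK (1.70) and CD74 (0.62). The B cell median was 0.48, or 0.47 with low-count members at their bounds (adjusted p = 0.00189, with an estimated correlation adjusted p = 0.168). Of 27 adhesion and homing genes, 11 rose, 3 fell and 13 did not pass (adjusted over the list alone, 12 rose and 4 fell), with log2 fold changes such as ITGAL (1.09) and ITGB7 (1.64). The adhesion median was 0.51, or 0.47 with low-count members at their bounds (adjusted p = 0.0109, with an estimated correlation adjusted p = 0.197). Of 13 stromal and epithelial markers, 5 rose and 8 did not pass (the same adjusted over the list alone), with log2 fold changes such as ACTA2 (2.36) and COL6A1 (2.03). The stromal median was 0.92, or 0.75 with low-count members at their bounds (adjusted p = 0.00336, with an estimated correlation adjusted p = 0.197). Of 25 apoptosis regulators, 8 rose, 2 fell and 15 did not pass (adjusted over the list alone, 9 rose and 2 fell), with log2 fold changes such as BMF (2.66), BCL2L11 (1.75), MCL1 (0.76) and BIRC5 (-1.35). The apoptosis median was 0.22 (adjusted p = 0.0301, with an estimated correlation adjusted p = 0.168). The apoptosis list was near the threshold. It did not pass in 10 of 12 fits without 1 library, all but those without AMO1 control 1 or AMO1 ID2-OE library 2. The fits that lost it included those without an H929 or KMS20 library, which are not part of this contrast. The other 11 lists did not pass (adjusted p 0.0653 to 0.732, with an estimated correlation 0.366 to 0.916). They were the ID and E protein genes, reported E protein targets in lymphocytes, D cyclins with CDKs and CDK inhibitors, p53 targets, NF-kB targets, glycolysis and hypoxia, nuclear OXPHOS, ribosomal proteins, small non-coding RNA genes, and the T/NK cell and myeloid markers. Among the 23 reported E protein targets, 3 rose, 7 fell and 13 did not pass (adjusted over the list alone, 4 rose and 8 fell); their median was 0.14 while their mean was -0.07 and the test pointed down. The ID and E protein list likewise had a median of 0.16 and a mean of -0.58, and the small non-coding RNA genes 0.20 and -0.01. The test also pointed down at a mean of 0.02 for the D cyclin list and a median of 0.02 for OXPHOS. Without single libraries some lists passed that otherwise did not. The NF-kB targets passed without AMO1 ID2-OE library 2 (0.0456) or either H929 ID2-OE library (0.0495 and 0.0493). The ribosomal proteins passed without AMO1 control 2 (0.0271) or ID2-OE library 2 (0.00180), and the myeloid markers without ID2-OE library 1 (0.0313). The glycolysis list passed without AMO1 control 1 (0.0432), ID2-OE library 1 (0.00420), KMS20 control 2 (0.0495) or KMS20 ID2-OE library 1 (0.0454) or 2 (0.0467).

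The third comparison asked the same of H929. In ID2-OE H929 cells all 148 tested genes of the replication, mitosis, histone and MYC-target lists fell, and the lists passed with camera's preset correlation but not with an estimated one (adjusted p = 0.142 to 0.276). CCND2, the most abundant D cyclin gene of the control lines, fell. Here 7839 genes were called (3773 rose, 4066 fell), 3839 of them by 2-fold or more. The share that rose was 48.1%, or 56.8% with DESeq2's size factors, so neither direction was the majority under both scalings. Rises were also the majority in each fit without 1 library, except that without AMO1 ID2-OE library 1. The median log2 fold change of all genes was 0, or 0.0853 with those factors. It was 0.0846 to 0.0862 in fits without 1 AMO1 or KMS20 library, except AMO1 ID2-OE library 1 (0). Single genes moved up too, as without KMS20 control 1 (CCND3 from -0.54 to -0.43, IRF4 from 0.34 to 0.45). Their calls that changed in those fits, given below, may therefore reflect scaling. ID2 rose from 31.4 ± 3.69 to 1367 ± 109.7 CPM (5.44 (SE 0.22, adjusted p = 7.42e-10)). ID3 fell (-0.79 (SE 0.23, adjusted p = 0.0101)), but not without control 1 (0.165) or ID2-OE library 2 (0.210). ID1 did not pass (-0.48 (SE 0.24, adjusted p = 0.110)), and passed without ID2-OE library 1 (-0.91, adjusted p = 0.00672). TCF3 rose from 449.9 to 619.7 CPM (0.46 (SE 0.12, adjusted p = 0.00541), or 0.69 without control 1) and TCF12 rose by 0.63 (adjusted p = 0.00138). TCF4 did not pass (0.03, adjusted p = 0.922). MYC fell from 274 ± 74.8 to 99.0 ± 9.85 CPM (-1.47 (SE 0.17, adjusted p = 5.03e-06)) and XBP1 from 2636 ± 176 to 1469.6 ± 11.1 CPM (-0.84 (SE 0.12, adjusted p = 2.33e-05)). E2F1 and MKI67 fell by 1.98 and 1.66 (adjusted p = 2.07e-06 and 3.72e-05). CCND2 fell from 223 ± 29.8 to 66.1 ± 0.927 CPM (-1.75 (SE 0.13, adjusted p = 1.07e-07)). CCND1 fell (-0.73 (SE 0.15, adjusted p = 0.000928)), with an adjusted p of 0.0551 without ID2-OE library 1. CCND3 fell (-0.54 (SE 0.17, adjusted p = 0.0138)), but its adjusted p was 0.0519 to 0.211 in 6 fits, those without H929 control 1, either H929 ID2-OE library, AMO1 ID2-OE library 2 or either KMS20 control. CDKN1A rose (0.56, adjusted p = 0.00549), as did PRDM1 (0.35, adjusted p = 0.0145, or 0.53 without control 1). IRF4 did not pass (0.34, adjusted p = 0.101), and rose with an adjusted p of 0.000401 to 0.0438 in 8 fits, those without H929 ID2-OE library 2, either AMO1 control, AMO1 ID2-OE library 2 or any KMS20 library.

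The largest rises in H929 included genes with 0 counts in the controls, and the largest falls ended at 0 counts. TBX18, GADD45G, CDH17, HLA-DQA1 and SLC7A7 rose from 0 counts, at least 37.7-, 35.1-, 26.7-, 4.55- and 3.90-fold. Without ID2-OE library 1 the adjusted p was 0.0551 for HLA-DQA1 and 0.146 for SLC7A7. IL2RB rose from 0.604 ± 0.167 to 27.9 ± 7.15 CPM (5.47 (SE 0.26, adjusted p = 3.59e-09)) and LGALS9 from 0.140 to 7.74 CPM (5.62 (SE 0.44, adjusted p = 1.62e-07)). With the 4 CPM minimum DOK2, DMBT1, GBP2, SATB1 and JAZF1 were among the rises, SATB1 from 0.874 to 20 CPM and GBP2 from 0.687 to 16.7 CPM. HIST1H4F fell from 23.7 CPM to 0 counts, at least 263-fold. How reads shared by histone genes were counted is not given in the sources used here, so this fall and those of the histone list may mix related genes. ZNF579, SHISAL2A, ZNF320, CACNG6, ZNF83, SYTL1 and SLC16A9 also fell to 0 counts, at least 32.8- to 3.59-fold. Such losses may also come from differences between the H929 cell populations other than ID2, which was not tested. The labels do not say how many derivatives each line had. SYTL1 did not pass without control 1 (0.124) or ID2-OE library 1 (0.0995) or 2 (0.125). With the 4 CPM minimum the falls included RASSF2, CTAG2, SLC7A2, ZNF788, AK4, MYB and TERT. The transcription factor gene MYB fell from 17.4 to 0.716 CPM (-4.60 (SE 0.28, adjusted p = 1.91e-08)), the telomerase gene TERT from 4.30 to 0.274 CPM (-3.97 (SE 0.41, adjusted p = 1.55e-06)), and the arginine transporter gene SLC7A2 from 26.8 to 0.656 CPM. RASSF2 stood 54.0 times (95% counting interval 18.3 to 263) higher in the controls.

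In H929, 11 of 24 lists passed with camera (5 higher, 6 lower), and none with an estimated correlation, which gave 3 at an unadjusted p under 0.05; fry gave 19. Of 40 G1/S and DNA replication genes, 40 fell (the same adjusted over the list alone), with log2 fold changes such as CDC25A (-3.34) and DTL (-3.10). The G1/S median was -2.11 (adjusted p = 6.95e-45, with an estimated correlation adjusted p = 0.142). Of 35 G2/M and mitosis genes, 35 fell (the same adjusted over the list alone), with log2 fold changes such as BUB1B (-2.14) and CCNA2 (-2.75). The G2/M median was -1.80 (adjusted p = 1.80e-19, with an estimated correlation adjusted p = 0.276). Of 43 replication-dependent histone genes, 43 fell (the same adjusted over the list alone), with log2 fold changes such as HIST1H4C (-2.34) and HIST1H3J (-2.80). The histone median was -2.27 (adjusted p = 3.37e-25, with an estimated correlation adjusted p = 0.276). Of 30 MYC targets, 30 fell (the same adjusted over the list alone), with log2 fold changes such as HSPD1 (-2.10), TFRC (-2.27) and WDR43 (-1.55). The MYC target median was -1.41 (adjusted p = 1.87e-22, with an estimated correlation adjusted p = 0.142). Of 29 glycolysis and hypoxia genes, 3 rose, 17 fell and 9 did not pass (adjusted over the list alone, 4 rose and 18 fell), with log2 fold changes such as LDHA (-1.39), PDK1 (-1.75) and HK2 (-1.35). The glycolysis median was -0.69 (adjusted p = 0.00194, with an estimated correlation adjusted p = 0.506). Of 23 cholesterol synthesis genes, 1 rose, 10 fell and 12 did not pass (the same adjusted over the list alone), with log2 fold changes such as DHCR7 (-1.62). The cholesterol median was -0.51 (adjusted p = 0.0477, with an estimated correlation adjusted p = 0.674). Without H929 control 1 the cholesterol list did not pass (0.0720).

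In H929 5 lists were higher with camera's preset correlation. Of 28 interferon-response genes, 17 rose, 1 fell and 10 did not pass (the same adjusted over the list alone), with log2 fold changes such as STAT2 (1.22), IRF9 (1.44) and SAMD9L (2.07). The interferon median was 1.02, or 1.11 with low-count members at their bounds (adjusted p = 0.000229, with an estimated correlation adjusted p = 0.276). Of 22 p53 targets, 11 rose, 2 fell and 9 did not pass (the same adjusted over the list alone), with log2 fold changes such as TP53INP1 (1.65) and BBC3 (1.97). The p53 target median was 0.52, or 0.48 with low-count members at their bounds (adjusted p = 0.0206, with an estimated correlation adjusted p = 0.290). Of 19 immediate early genes, 11 rose and 8 did not pass (adjusted over the list alone, 11 rose and 1 fell), with log2 fold changes such as JUN (2.81) and EGR1 (2.38). The immediate early median was 0.89 (adjusted p = 0.0107, with an estimated correlation adjusted p = 0.611). Of 23 B cell genes, 9 rose and 14 did not pass (the same adjusted over the list alone), with log2 fold changes such as HLA-DPA1 (3.22) and BANK1 (2.76). The B cell median was 1.11, or 1.17 with low-count members at their bounds (adjusted p = 0.0111, with an estimated correlation adjusted p = 0.276). Of 7 T and NK cell markers, 4 rose and 3 did not pass (the same adjusted over the list alone), with log2 fold changes such as PRF1 (3.46) and CD3E (1.46). The T/NK marker median was 3.46, or 3.50 with low-count members at their bounds (adjusted p = 0.00962, with an estimated correlation adjusted p = 0.174). Without H929 ID2-OE library 1 the B cell list did not pass (0.0982), nor did the immediate early list without control 2 (0.0646). The other 13 lists did not pass (adjusted p 0.0933 to 0.853, with an estimated correlation 0.276 to 0.916). They were the ID and E protein genes, reported E protein targets, D cyclins with CDKs and CDK inhibitors, plasma cell genes, the unfolded protein response, NF-kB targets, apoptosis regulators, adhesion and homing, OXPHOS, ribosomal proteins, small non-coding RNA genes, and the myeloid and stromal markers. Among the 23 reported E protein targets, 9 rose, 7 fell and 7 did not pass (adjusted over the list alone, 9 rose and 8 fell), with E2F2 at -2.82 and SOCS3 at 1.73. Of the plasma cell genes 3 rose, 11 fell and 9 did not pass (the same adjusted over the list alone), and of the apoptosis regulators 9 rose, 3 fell and 13 did not pass (the same adjusted over the list alone), with BCL2L11 at 2.55. The D cyclin list had a median of -0.20 and a mean of 0.11, and the unfolded protein list -0.03 and 0.07. The NF-kB targets passed without control 1 (0.0400), and OXPHOS without AMO1 ID2-OE library 1 (0.0375).

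The fourth comparison concerned KMS20. CDKN1A and TCF4 rose in ID2-OE KMS20 cells, and MYC and XBP1 fell. The replication and MYC-target lists were lower (38 of 40 and 30 of 30 genes fell) with camera's preset correlation, but did not pass with an estimated one (adjusted p = 0.262 and 0.0830). In total 6068 genes were called (3096 rose, 2972 fell), 2436 of them by 2-fold or more. ID2 rose from 39.5 ± 5.58 to 2151 ± 19.1 CPM (5.76 (SE 0.22, adjusted p = 6.66e-10)). ID1 fell from 24.5 to 3.88 CPM (-2.65 (SE 0.28, adjusted p = 4.75e-06)) and ID3 from a low level of 1.74 CPM (-1.38 (SE 0.47, adjusted p = 0.0290)). Without control 1, control 2 or ID2-OE library 1 the adjusted p of ID3 was 0.0542, 0.0766 and 0.250. TCF4 rose from 368 to 823 CPM (1.16 (SE 0.16, adjusted p = 5.46e-05)). TCF3 did not pass (-0.29 (SE 0.12, adjusted p = 0.0700)); without H929 control 1 or 2 it fell at 0.0432 or 0.0428. TCF12 did not pass (-0.18, adjusted p = 0.321), nor did CCND2 (0.12, adjusted p = 0.465) and IRF4 (-0.10, adjusted p = 0.690). CCND1 had 0 counts in the controls and 1 in ID2-OE. MYC fell from 699 ± 67.3 to 197 ± 21.6 CPM (-1.83 (SE 0.17, adjusted p = 1.73e-06)) and XBP1 from 485 ± 41.1 to 203 ± 15.5 CPM (-1.26 (SE 0.12, adjusted p = 1.63e-06)). CDKN1A rose from a low level, from 0.349 to 2.02 CPM (2.44 (SE 0.36, adjusted p = 9.23e-05)), and PRDM1 rose from 218 to 420.2 CPM (0.95 (SE 0.11, adjusted p = 1.11e-05)). E2F1 fell by 0.90 (adjusted p = 0.00206) and CCND3 by 0.79 (adjusted p = 0.00230, or 0.0513 without ID2-OE library 1). MKI67 did not pass (-0.49, adjusted p = 0.107), and fell without H929 ID2-OE library 1 or 2 (0.0151 both times).

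The largest rises in KMS20 included the cytokine gene IL10, and the largest falls the hexokinase gene HK2. With the 4 CPM minimum the largest rises beside ID2 were IL10, CHRNA1, GFI1, ENPP2, CALCOCO1, YPEL3 and LRRN1. IL10 rose from 4.66 to 79.8 CPM (4.09 (SE 0.22, adjusted p = 3.69e-08)), the transcriptional repressor gene GFI1 from 1.57 to 18.4 CPM (3.56 (SE 0.19, adjusted p = 1.71e-08)) and the autophagy receptor gene CALCOCO1 from 30.0 to 260.4 CPM (3.12 (SE 0.14, adjusted p = 3.39e-09)). Without that minimum the rises came from genes near 0 counts in the controls. CEACAM1, LDHD, ADAMTS12 and PKHD1 rose from 0 counts, at least 4.63-, 3.60-, 3.60- and 3.09-fold. DNER, TNFRSF8 and LILRB1 rose to 32.4 times (95% counting interval 5.22 to 1342), 23.2 times (95% counting interval 3.57 to 976) and 20.1 times (95% counting interval 5.03 to 175) the control level. ADAMTS12 was lost without control 1 (0.0679), LDHD without control 1 (0.0782), control 2 (0.0526) or ID2-OE library 1 (0.0562), and PKHD1 without control 1 (0.0880), control 2 (0.0596) or ID2-OE library 2 (0.116). HK2 fell from 169 to 22.6 CPM (-2.91 (SE 0.15, adjusted p = 1.71e-08)), and the threonine-degrading enzyme gene GCAT from 5.81 to 0.716 CPM (-2.94 (SE 0.36, adjusted p = 1.71e-05)). STC2, DDN, KCTD15, SLC7A2 and C17ORF51 were among the falls with the 4 CPM minimum. TLR7, PLAC8 and CMBL fell to 0 counts, at least 5.18-, 2.37- and 1.29-fold, and RIMKLA and NMRAL1 stood 7.98 times (95% counting interval 2.53 to 40.5) and 8.09 times (95% counting interval 2.02 to 70.5) higher in the controls. CMBL had only 6 counts in the controls, so its bound does not exclude an unchanged level. Without ID2-OE library 1 the adjusted p of TLR7, PLAC8 and RIMKLA was 0.0566, 0.0800 and 0.0627, and that of CMBL was 0.0641 to 0.212 without any of the 4 KMS20 libraries.

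In KMS20, 15 of 24 lists passed with camera (5 higher, 10 lower), and none with an estimated correlation, which gave 4 at an unadjusted p under 0.05; fry gave 21. Of 30 MYC targets, 30 fell (the same adjusted over the list alone), with log2 fold changes such as ODC1 (-1.83), HSPD1 (-1.75) and NOLC1 (-1.49). The MYC target median was -1.49 (adjusted p = 7.72e-37, with an estimated correlation adjusted p = 0.0830). Of 40 G1/S and DNA replication genes, 38 fell and 2 did not pass (adjusted over the list alone, 39 fell), with log2 fold changes such as CDC6 (-1.87) and PCNA (-1.53). The G1/S median was -1.22 (adjusted p = 6.68e-24, with an estimated correlation adjusted p = 0.262). Of 35 G2/M and mitosis genes, 14 fell and 21 did not pass (the same adjusted over the list alone), with log2 fold changes such as BIRC5 (-0.77) and BUB1B (-0.81). The G2/M median was -0.49 (adjusted p = 0.000773, with an estimated correlation adjusted p = 0.556). Of 43 replication-dependent histone genes, 1 rose, 37 fell and 5 did not pass (the same adjusted over the list alone), with log2 fold changes such as HIST1H4C (-1.10). The histone median was -1.0, or -0.99 with low-count members at their bounds (adjusted p = 1.85e-08, with an estimated correlation adjusted p = 0.477). Of 23 plasma cell genes, 2 rose, 11 fell and 10 did not pass (adjusted over the list alone, 2 rose and 12 fell), with log2 fold changes such as SDC1 (-2.47) and MZB1 (-2.64). The plasma cell median was -0.70, or -0.71 with low-count members at their bounds (adjusted p = 0.000335, with an estimated correlation adjusted p = 0.389). Of 26 unfolded protein and ER stress genes, 2 rose, 12 fell and 12 did not pass (adjusted over the list alone, 2 rose and 16 fell), with log2 fold changes such as MANF (-1.46) and SDF2L1 (-1.79). The ER stress median was -0.40 (adjusted p = 0.00129, with an estimated correlation adjusted p = 0.467). Of 23 cholesterol synthesis genes, 16 fell and 7 did not pass (adjusted over the list alone, 18 fell), with log2 fold changes such as EBP (-1.05). The cholesterol median was -0.65 (adjusted p = 1.20e-05, with an estimated correlation adjusted p = 0.433). Of 29 glycolysis and hypoxia genes, 4 rose, 16 fell and 9 did not pass (adjusted over the list alone, 5 rose and 16 fell), with log2 fold changes such as LDHA (-1.45), SLC2A1 (-1.53) and ENO1 (-1.22). The glycolysis median was -0.77 (adjusted p = 5.79e-05, with an estimated correlation adjusted p = 0.433).

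A further 7 lists passed in KMS20 with camera's preset correlation, 2 lower and 5 higher, each with many members that did not pass. Of 31 nuclear OXPHOS genes, 17 fell and 14 did not pass (the same adjusted over the list alone), with log2 fold changes such as ATP5G1 (-1.59) and ATP5B (-0.67). The OXPHOS median was -0.38 (adjusted p = 0.000773, with an estimated correlation adjusted p = 0.477). Of 50 ribosomal protein genes, 22 fell and 28 did not pass (the same adjusted over the list alone), with log2 fold changes such as RPL35 (-0.77) and RPS16 (-0.60). The ribosomal protein median was -0.33 (adjusted p = 0.000194, with an estimated correlation adjusted p = 0.513). Of 28 interferon-response genes, 14 rose, 2 fell and 12 did not pass (adjusted over the list alone, 16 rose and 2 fell), with log2 fold changes such as STAT2 (1.52) and IRF9 (2.29). The interferon median was 0.77 (adjusted p = 0.00151, with an estimated correlation adjusted p = 0.433). Of 19 NF-kB targets, 10 rose, 1 fell and 8 did not pass (adjusted over the list alone, 13 rose and 1 fell), with log2 fold changes such as TNFAIP3 (1.21) and BIRC3 (1.45). The NF-kB median was 0.66, or 0.72 with low-count members at their bounds (adjusted p = 0.000773, with an estimated correlation adjusted p = 0.256). Of 19 immediate early genes, 9 rose, 1 fell and 9 did not pass (the same adjusted over the list alone), with log2 fold changes such as KLF6 (1.24), DUSP5 (1.48) and DUSP2 (-2.17). The immediate early median was 1.12 (adjusted p = 0.00293, with an estimated correlation adjusted p = 0.477). Of 25 apoptosis regulators, 11 rose, 3 fell and 11 did not pass (the same adjusted over the list alone), with log2 fold changes such as MCL1 (1.72), BMF (1.92) and BCL2 (1.45). The apoptosis median was 0.30, or 0.40 with low-count members at their bounds (adjusted p = 0.00293, with an estimated correlation adjusted p = 0.154). Of 13 stromal and epithelial markers, 7 rose, 2 fell and 4 did not pass (the same adjusted over the list alone), with log2 fold changes such as ACTA2 (3.02) and EPCAM (-2.13). The stromal median was 0.70 (adjusted p = 0.0304, with an estimated correlation adjusted p = 0.433). Without KMS20 control 1 the stromal list did not pass (0.0619). The other 9 lists did not pass (adjusted p 0.0865 to 0.901, with an estimated correlation 0.467 to 0.956). They were the ID and E protein genes, reported E protein targets, D cyclins with CDKs and CDK inhibitors, B cell genes, p53 targets, adhesion and homing, small non-coding RNA genes, and the T/NK cell and myeloid markers. Among the 23 reported E protein targets, 8 rose, 5 fell and 10 did not pass (the same adjusted over the list alone), and among the 22 p53 targets, 10 rose, 4 fell and 8 did not pass (the same adjusted over the list alone). The myeloid markers, of which 1 rose, had a mean of -1.01 although the test pointed up.

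The fifth comparison averaged the 3 lines with equal weight and asked for a common response. In all 3 lines MYC and XBP1 fell. E2F1 and ID3 also fell and PRDM1 rose in each, though in at least 1 line each of these 3 calls was lost when single libraries were left out. The replication, histone and MYC-target lists were lower in each line with camera's preset correlation, and on average did not pass with an estimated one (adjusted p = 0.143, 0.290 and 0.118). On average 8289 genes were called (4223 rose, 4066 fell), 2256 of them by 2-fold or more, and 2189 genes were called in the same direction in all 3 lines (1038 rose, 1151 fell). With DESeq2's size factors 1157 rose and 1089 fell, so the balance of the shared genes depended on the scaling. Without AMO1 ID2-OE library 2 the lines shared 1406. Independent lists of these sizes would share 115 and 94.5, though genes are not independent. Pairs of lines shared 1373 to 1759 rises and 1269 to 2109 falls, while 122 genes rose in H929 and fell in KMS20 and 104 did the reverse. Opposite calls were fewer for AMO1, with 55 rises that fell in H929 and 59 falls that rose there, and 48 and 27 in KMS20. The lines had separate controls, so no control library was shared. Across genes, the Spearman correlation of log2 fold changes was 0.587 for AMO1 and H929, 0.558 for AMO1 and KMS20 and 0.542 for H929 and KMS20 (Pearson 0.445, 0.426 and 0.406). The average changes were 5.84 (SE 0.13, adjusted p = 1.44e-13) for ID2, -1.46 (SE 0.10, adjusted p = 1.10e-08) for MYC, -0.98 (SE 0.07, adjusted p = 1.44e-08) for XBP1 and -1.25 (SE 0.12, adjusted p = 3.05e-07) for E2F1. ID1 and ID3 fell by 1.98 and 1.68 (adjusted p = 9.27e-08 and 2.51e-06), and MKI67 by 1.06 (adjusted p = 7.28e-06). TCF4 and TCF12 rose by 0.80 and 0.23 (adjusted p = 3.36e-06 and 0.0205). TCF3 did not pass (0.08 (SE 0.07, adjusted p = 0.387)), and with a trend in GC content and transcript length taken out, an alternative chosen after seeing the data, it fell by 0.14 (adjusted p = 0.0290). CCND2 and CCND3 fell by 0.61 and 0.59 (adjusted p = 3.36e-06 and 0.000102), and CDKN1A and PRDM1 rose by 0.91 and 0.55 (adjusted p = 4.70e-05 and 2.31e-06). The p-values of these averages rest on the spread between libraries, not between lines. A large change in 1 line can therefore carry an average. On their own lines, CCND2 and TCF12 were called in H929 alone, and CDKN1A and CCND3 were not called in AMO1. TCF4 and ID1 were not called in H929, nor MKI67 in KMS20. IRF4 did not pass (adjusted p = 0.348), and fell without H929 ID2-OE library 1 (-0.22, adjusted p = 0.0163). CCND1 did not pass (adjusted p = 0.335).

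**Figure D1:**
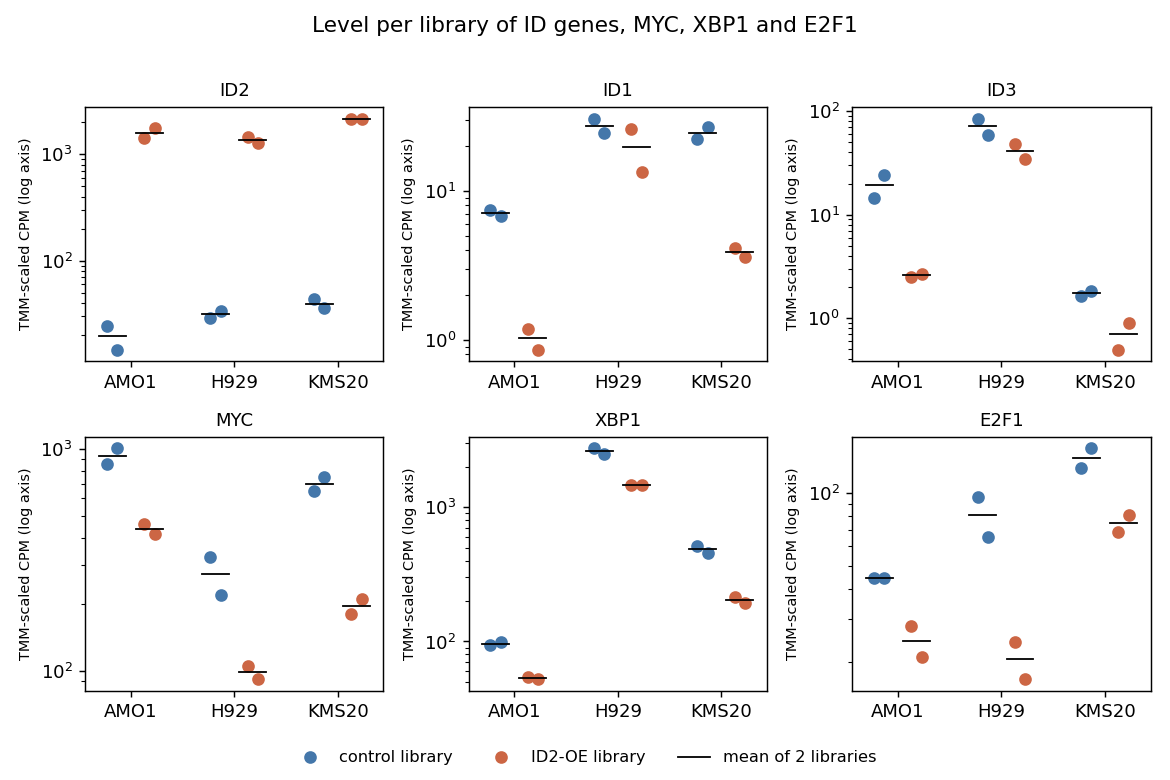
Level of ID2, ID1, ID3, MYC, XBP1 and E2F1 in each library (vertical axis, CPM, log scale) by line and arm; points are libraries and short lines the mean of the 2 libraries of a group. In each line the MYC mean was lower in ID2-OE than in control, from 933 to 437 CPM in AMO1, 274 to 99.0 in H929 and 699 to 197 in KMS20.

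The genes with the largest average rises were ID2, GBP2, SATB1, ENPP2, IL2RB, CEACAM1, CHRNA1 and LDHD. SATB1 and IL2RB, a subunit of the interleukin-2 receptor, rose by 3.58 (SE 0.16, adjusted p = 3.33e-10) and 3.55 (SE 0.13, adjusted p = 8.33e-11), and in each line on its own. With the 4 CPM minimum LGALS9, GSN, TMEM140, ACTA2 and SYNPO joined them, GSN rising by 2.88 (SE 0.14, adjusted p = 8.70e-10) and TMEM140 by 2.86 (SE 0.12, adjusted p = 1.99e-10). GBP2 had 3 counts in the KMS20 controls and stood there at 1.29 CPM in ID2-OE, and CEACAM1 and LDHD had 0 counts in the KMS20 controls. ENPP2 had 0 counts in the H929 controls, and its average did not pass without H929 ID2-OE library 1 (0.0759). CHRNA1 had 1 count in the AMO1 and 1 in the H929 controls and rose mainly in KMS20, from 4.22 to 65.5 CPM. The largest falls were SLC16A9, HIST1H3C, AK4, POLR3G, TERT, MYB, MEST and HSPE1. POLR3G, a subunit of RNA polymerase III, fell by 2.47 (SE 0.15, adjusted p = 3.53e-09), TERT by 2.47 (adjusted p = 1.90e-08) and MYB by 2.38 (adjusted p = 1.41e-09). RRM2, DSCC1 and MCM10, all of DNA synthesis, joined with the 4 CPM minimum, MCM10 falling by 2.11 (SE 0.12, adjusted p = 2.35e-09). SLC16A9 and MEST were at 0 and 1 counts in H929 ID2-OE. HIST1H3C, at 4 and 0 counts in the KMS20 arms, was lost on average without AMO1 ID2-OE library 2 (0.0508) or any KMS20 library (adjusted p 0.0586 to 0.0928).

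On average 14 of 24 lists passed with camera (5 higher, 9 lower), and none with an estimated correlation, which gave 4 at an unadjusted p under 0.05; fry gave 18. Of 40 G1/S and DNA replication genes, 40 fell (the same adjusted over the list alone), with log2 fold changes such as CDC6 (-1.97), CDC25A (-2.11) and PCNA (-1.54). The G1/S median was -1.46 (adjusted p = 1.69e-42, with an estimated correlation adjusted p = 0.143). Of 30 MYC targets, 30 fell (the same adjusted over the list alone), with log2 fold changes such as HSPD1 (-1.56), TFRC (-1.63) and NOLC1 (-1.22). The MYC target median was -1.14 (adjusted p = 1.11e-30, with an estimated correlation adjusted p = 0.118). Of 43 replication-dependent histone genes, 41 fell and 2 did not pass (the same adjusted over the list alone), with log2 fold changes such as HIST1H4C (-1.55) and HIST1H3J (-1.87). The histone median was -1.5 (adjusted p = 1.01e-22, with an estimated correlation adjusted p = 0.290). Of 35 G2/M and mitosis genes, 34 fell and 1 did not pass (adjusted over the list alone, 35 fell), with log2 fold changes such as BUB1B (-1.43) and CCNB1 (-1.33). The G2/M median was -1.19 (adjusted p = 2.94e-20, with an estimated correlation adjusted p = 0.290). Of 23 cholesterol synthesis genes, 18 fell and 5 did not pass (the same adjusted over the list alone). The cholesterol median was -0.65 (adjusted p = 3.46e-05, with an estimated correlation adjusted p = 0.384). Of 29 glycolysis and hypoxia genes, 5 rose, 16 fell and 8 did not pass (the same adjusted over the list alone), with log2 fold changes such as HK2 (-1.63), LDHA (-1.17) and PDK1 (-1.10). The glycolysis median was -0.54 (adjusted p = 0.000549, with an estimated correlation adjusted p = 0.402). Of 23 plasma cell genes, 2 rose, 11 fell and 10 did not pass (the same adjusted over the list alone), with log2 fold changes such as SDC1 (-1.33), XBP1 (-0.98) and DERL3 (-1.54). The plasma cell median was -0.16, or -0.30 with low-count members at their bounds (adjusted p = 0.00987, with an estimated correlation adjusted p = 0.384). Of 26 unfolded protein and ER stress genes, 4 rose, 15 fell and 7 did not pass (adjusted over the list alone, 5 rose and 16 fell), with log2 fold changes such as PDIA4 (-0.74) and HSP90B1 (-0.70). The ER stress median was -0.24 (adjusted p = 0.0183, with an estimated correlation adjusted p = 0.502). Of 31 nuclear OXPHOS genes, 1 rose, 16 fell and 14 did not pass (adjusted over the list alone, 2 rose and 16 fell), with log2 fold changes such as ATP5G1 (-0.98). The OXPHOS median was -0.22 (adjusted p = 0.0295, with an estimated correlation adjusted p = 0.655). Without AMO1 ID2-OE library 2 the OXPHOS list did not pass (0.0511).

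**Figure D2:**
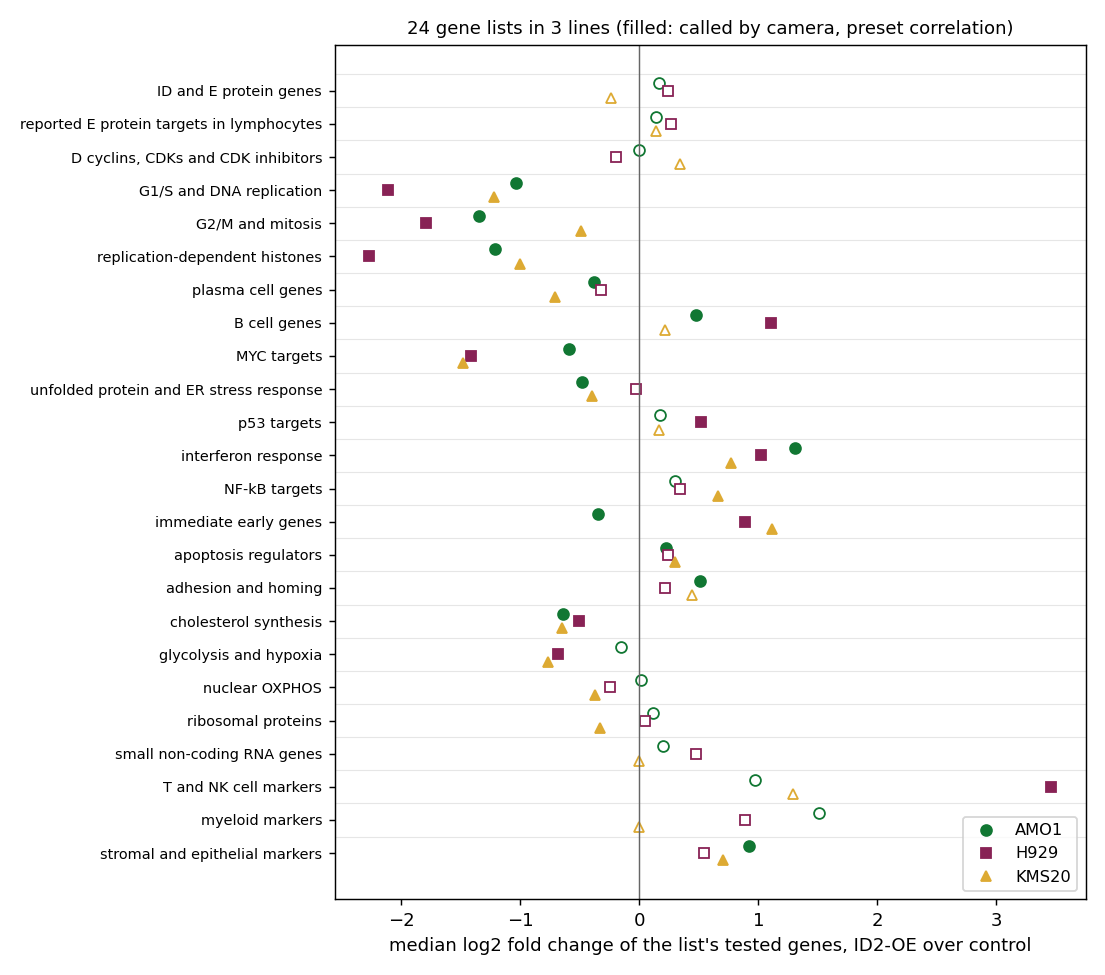
Median log2 fold change (ID2-OE over control, horizontal axis) of the tested members of 24 gene lists in AMO1, H929 and KMS20; filled symbols mark lists that passed with camera at its preset correlation. The G1/S and DNA replication list had medians of -1.04, -2.11 and -1.22, and the interferon response 1.31, 1.02 and 0.77.

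The 5 lists that were higher on average were those of the interferon response, NF-kB targets, apoptosis regulators, p53 targets, and stromal and epithelial markers, none of which passed with an estimated correlation. Of 28 interferon-response genes, 20 rose, 1 fell and 7 did not pass (the same adjusted over the list alone), with log2 fold changes such as STAT2 (1.21), IRF9 (1.64) and OAS1 (1.17). The interferon median was 1.14 (adjusted p = 1.00e-07, with an estimated correlation adjusted p = 0.176). Of 19 NF-kB targets, 12 rose, 1 fell and 6 did not pass (the same adjusted over the list alone), with log2 fold changes such as NFKBIA (0.88) and NFKB2 (0.65). The NF-kB median was 0.65, or 0.32 with low-count members at their bounds (adjusted p = 0.0139, with an estimated correlation adjusted p = 0.290). Of 25 apoptosis regulators, 11 rose, 3 fell and 11 did not pass (the same adjusted over the list alone), with log2 fold changes such as BMF (2.14), BCL2L11 (1.72) and BIRC5 (-1.29). The apoptosis median was 0.17 (adjusted p = 0.00987, with an estimated correlation adjusted p = 0.143). Of 22 p53 targets, 12 rose, 4 fell and 6 did not pass (adjusted over the list alone, 13 rose and 4 fell), with log2 fold changes such as TP53INP1 (1.68), TP53I3 (1.51) and AEN (-0.83). The p53 target median was 0.34, or 0.48 with low-count members at their bounds (adjusted p = 0.0295, with an estimated correlation adjusted p = 0.348). Of 13 stromal and epithelial markers, 8 rose, 1 fell and 4 did not pass (the same adjusted over the list alone), with log2 fold changes such as ACTA2 (2.85) and CDH1 (1.46). The stromal median was 0.86, or 0.90 with low-count members at their bounds (adjusted p = 0.0124, with an estimated correlation adjusted p = 0.290). The other 10 lists did not pass (adjusted p 0.0906 to 0.960, with an estimated correlation 0.390 to 0.972). They were the ID and E protein genes, reported E protein targets, D cyclins with CDKs and CDK inhibitors, B cell genes, immediate early genes, adhesion and homing, ribosomal proteins, small non-coding RNA genes, and the T/NK cell and myeloid markers. The 23 reported E protein targets split: 8 rose, 6 fell and 9 did not pass (the same adjusted over the list alone), with E2F2 at -1.78 and GFI1 at 1.31, and the test pointed down although their median was 0.19 and their mean 0.20. The D cyclin, CDK and inhibitor list split too: 7 rose, 6 fell and 3 did not pass (the same adjusted over the list alone), with CDK4 at -1.06 and the inhibitor genes CDKN2B and CDKN1B at 1.97 and 0.78. The ID and E protein list had a median of 0.16 and a mean of -0.20. B cell genes passed without H929 ID2-OE library 2 (0.0415) or KMS20 control 2 (0.0484), and immediate early genes without AMO1 ID2-OE library 1 (0.0463), H929 control 1 (0.0382) or H929 ID2-OE library 2 (0.00988). None of the 15 mitochondrially encoded genes was in the file, and 1 of 15 immunoglobulin constant genes was, so neither list was tested.

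**Figure D3:**
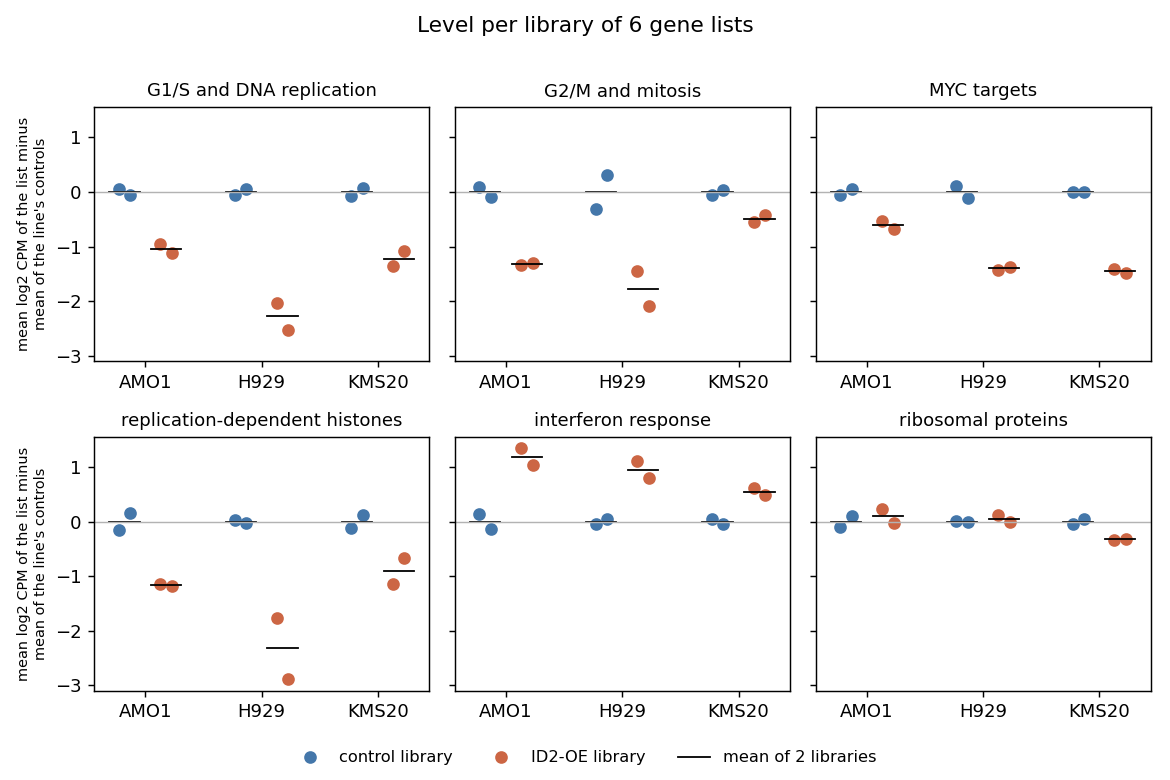
Mean log2 CPM of 6 gene lists in each library minus the mean of the line's control libraries (vertical axis), by line and arm; points are libraries. The 2 ID2-OE libraries of each line lay below its controls for the G1/S and DNA replication list.

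The last comparison asked whether ID2 overexpression acted differently in the 3 lines. Some genes, such as PECAM1 and CLEC7A, moved in opposite directions between lines. The interaction test called 3341 genes, or 5283 with a trend in GC content and transcript length taken out, an alternative chosen after seeing the data. Its smallest adjusted p-values were those of GFI1, PECAM1, FUCA1 and PEG10 (each 3.45e-06) and of KAT6A, RUNX3, CLEC7A and RASSF2 (each 3.71e-06). GFI1 changed by 0.14, 0.23 and 3.56 in AMO1, H929 and KMS20. PECAM1, an adhesion receptor gene, changed by 3.01, -3.05 and 1.04, and the lectin receptor gene CLEC7A by 3.02, -1.88 and 2.48. In AMO1 most of the few control counts of PECAM1 came from control 1. FUCA1 changed by 0.62, 3.66 and 1.78, KAT6A by 0.22, -1.71 and 0.32 and RUNX3 by 0.54, 2.77 and 0.59. PEG10 changed by 1.14 in AMO1 and -1.44 in KMS20 and was near 0 counts in H929, while RASSF2 fell in H929 from 4.91 to 0.0933 CPM and rose in KMS20 from 6.38 to 17.1 CPM. Of the 16 panel genes 12 differed between lines, with CCND2 (-0.21, -1.75 and 0.12, adjusted p = 2.02e-05) and CDKN1A (-0.27, 0.56 and 2.44, adjusted p = 0.000628) the clearest. TCF3 also differed (0.07, 0.46 and -0.29, adjusted p = 0.0166). ID2, CCND3, MYC and XBP1 did not (adjusted p = 0.0622, 0.534, 0.0840 and 0.107). Differences of whole lists between lines passed with camera for 16 of the 24 fixed lists, none with an estimated correlation. The G1/S list fell further in H929 than in AMO1 (adjusted p = 2.43e-28, with an estimated correlation adjusted p = 0.297), and MYC targets further in KMS20 than in AMO1 (1.20e-23, with an estimated correlation adjusted p = 0.199). Immediate early genes were lower in AMO1 and higher in KMS20 (2.27e-13, with an estimated correlation adjusted p = 0.199). The number of called interactions was 2082, 1969, 1977 and 2028 without KMS20 control 1, control 2, ID2-OE library 1 and ID2-OE library 2.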

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

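The tests of depth, GC content with transcript length, scaling between libraries, reads from another line, and the spread shared by the groups were chosen only after the result was seen; that of other splits, and the fits of each line alone, were chosen before. The genes and lists given with an adjusted p were singled out because the ID2 effect differed between the lines in a test of the difference itself. Groups of 2 libraries are too small to test for a library far from the others. The 8 named genes with the smallest adjusted p were GFI1, PECAM1, FUCA1 and PEG10 (3.45e-06) and KAT6A, RUNX3, CLEC7A and RASSF2 (3.71e-06). Of the panel genes, 12 differed: ID1 (0.000863), ID3 (0.00329), TCF3 (0.0166), TCF4 (0.00339), TCF12 (0.0217), CCND1 (0.0308), CCND2 (2.02e-05), CDKN1A (0.000628), IRF4 (0.0295), PRDM1 (0.0159), E2F1 (0.0155) and MKI67 (0.0491). Of the 258 other named genes, 164 differed.

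Among the fixed lists 16 of 24 differed between a pair of lines with camera, none of them with an estimated correlation; the pair with the smallest p, adjusted over the 24 lists of that pair, is given. AMO1 and H929 differed for ID and E protein genes (0.0320), G1/S and DNA replication (2.43e-28), B cell genes (0.0278), the unfolded protein response (1.75e-06) and p53 targets (0.00535). AMO1 and KMS20 differed for reported E protein targets (2.61e-05), MYC targets (1.20e-23), the interferon response (0.0120), NF-kB targets (0.00107), immediate early genes (2.27e-13), glycolysis and hypoxia (0.000336), nuclear OXPHOS (1.18e-05) and ribosomal proteins (5.47e-11). H929 and KMS20 differed for G2/M and mitosis (5.72e-18), histones (8.47e-14) and plasma cell genes (0.00472).

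The G1/S, G2/M, histone and MYC-target lists together (148 tested genes) had medians of -1.11, -1.94 and -1.06 in AMO1, H929 and KMS20. The KMS20 fall was uneven: the median was -1.49 for MYC targets and -0.49 for G2/M, where 21 of 35 genes did not pass. With all libraries thinned to the smallest total the line closest to 0 kept a median of -1.0. Thinning keeps each gene's expected share of its library, so this median could hardly move and cannot decide on depth. With the GC and length trend taken out the line closest to 0 kept -0.97, which argues against that trend. A scaling factor moves all genes of a library alike. The median of the 148 genes minus that of all genes was -1.08 in the line closest to 0, which argues against scaling. Fewer dividing cells or less transcription of these genes in ID2-OE cells is a candidate explanation. Differences between the cell populations other than ID2 stay open, since the labels do not say how many derivatives each line had.

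In AMO1, MMP9, TBX18, GLB1L2, MTUS1 and SYNM rose from 0 counts and were abundant in another line, as reads or cells of that line in the AMO1 ID2-OE libraries could also give. Of 155 genes absent from the AMO1 controls and at least as abundant elsewhere, 94.2% lay below 0.1 of the level the 5 genes' median ratio of 1.30% gives, and 99 had 0 counts where the typical expected count was 26.4; this argues against that source for the 5 genes. For APP, at a ratio of 0.0462%, the other 151 genes held 116 counts where 296 were needed (0.392 times), which lies between the bounds set for either answer, so a source in another line and a rise in AMO1 cannot be told apart for APP.

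H929 had the most called genes, 1.29 times the next line. It kept the most with libraries thinned to the smallest total (1.22 times) and with the GC and length trend taken out (1.16 times), which argues against both. Against a fold change of 1.5 (glmTreat), which also uses the shared spread, H929 had 1.80 times the genes of the next line. With each line fitted alone KMS20 came first and the ratio was 0.814, so the order of the lines may come from the spread that the 6 groups share.

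For the average over the lines, 100 of the 108 splits within lines were drawn. The real split gave 8289 genes and the highest other 4974, and 1 of 100, the real one, was as large. A chance assignment of these libraries to the arms would thus seldom give so many genes. The splits cannot exclude a chance difference between cultures, because the libraries of a group may come from the same culture. The real split gave 14 lists and the highest other 17, and 8 of 100, the real one included, were as large, so chance cannot be excluded for the lists. The median over the other splits was 9 lists and 0 genes. In splits that mix the arms, the ID2 effect enters the spread within groups, which lowers the gene calls. These medians therefore do not show how often lists pass by chance. With 8 of 100 splits as large, the number of lists decides little.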

How the results depend on the processing

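The GC and length trend, thinning and the 4 CPM minimum were chosen only after the result was seen; the other alternatives were chosen before. A value not called in either fit was counted as the same whatever its sign. Against a fold change of 1.5 (glmTreat), which tests a stricter question, 1017, 3896, 2162 and 2765 genes remained past the threshold in AMO1, H929, KMS20 and the average, and 319 in the same direction in all 3 lines. The counts of genes stayed within 1.5 times the reported ones with DESeq2's size factors, library totals, either filter, DESeq2, limma-voom, the additive model (7924) and thinning. Among genes with 4 CPM or more, 3412, 6379, 5177 and 6232 were called in AMO1, H929, KMS20 and on average. With the GC and length trend taken out the genes differing between lines rose to 5283, and TCF3 on average turned from 0.08 to -0.14 (adjusted p = 0.0290); the cause was not tested. Fitted alone, AMO1, H929 and KMS20 gave 3971, 6597 and 8106 genes. With a replicate block by title number they gave 3634, 7629 and 5842, the average 8076, the interaction 2803 and the shared set 1969; the numbers do not pair the samples. The share of rises turned with the setting: in AMO1 it was 55.6%, 46.8% without AMO1 control 2 and 64.3% with glmTreat; in H929 48.1%, and 56.8% with DESeq2's size factors; in KMS20 51.0%, and 45.7% with no filter; for the shared genes 47.4%, 51.5% with DESeq2's size factors and 63.0% with glmTreat. The median of all genes passed 0.1 with no filter (0.11, average), DESeq2 (0.10, average) and without H929 control 2 (0.11, H929).

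Leaving out each library in turn, with a lone library assumed to vary like the other groups, gave 2428 to 4732 genes in AMO1, 6135 to 8117 in H929, 4064 to 6622 in KMS20, 7596 to 8530 on average, 1969 to 4051 differing between lines and 1406 to 2453 shared. AMO1 had 2530 without AMO1 control 1 and 2428 without AMO1 ID2-OE library 2, which also gave the 1406 shared. The genes differing between lines were 2082, 1969, 1977 and 2028 without KMS20 control 1, control 2, ID2-OE library 1 and library 2; the cause was not tested. The lists ranged from 12 to 15 in AMO1, 10 to 12 in H929, 14 to 15 in KMS20 and 13 to 16 on average.

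With an estimated correlation the called lists went to 0 in AMO1, 0 in H929, 0 in KMS20 and 0 on average (6, 3, 4 and 4 at an unadjusted p under 0.05, and 16, 19, 21 and 18 by fry). With fry H929 thus had 19; fry compares a list with no other genes. Of 96 list values, 43 kept their side of the threshold with an estimated correlation (53 weaker), 71 with fry (2 weaker, 23 stronger), 94 with DESeq2's size factors (2 weaker) and 88 with the GC and length trend taken out (4 weaker, 4 stronger). Of 512 named-gene values, 509 did with DESeq2's size factors, 509 with library totals, 508 with limma-voom and 502 with the title block, and 499 of 511 with DESeq2; between 487 and 504 did without 1 library. Depth limits the genes near 0 counts, whose folds are bounds or wide intervals.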

Other observations

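The lists here, and the genes named from them, were chosen only after the result was seen, so their p-values describe these samples and test nothing independently. Of 28 quiescence and FOXO-associated genes, 25 rose and 3 did not pass on average, with log2 fold changes such as YPEL3 (2.56), CALCOCO1 (2.34) and TP53INP1 (1.68). The quiescence median was 1.34, or 1.52 with low-count members at their bounds (camera adjusted p = 9.13e-23, with an estimated correlation adjusted p = 0.00187). Some of them are also p53 targets, apoptosis regulators or CDK inhibitors of the fixed lists. By line the medians were 0.74, 1.57 and 1.76 in AMO1, H929 and KMS20. Of 19 purine and pyrimidine synthesis genes, 17 fell and 2 did not pass on average, with log2 fold changes such as PPAT (-1.32) and CAD (-1.02). The nucleotide median was -0.97, or -1.0 with low-count members at their bounds (camera adjusted p = 2.40e-15, with an estimated correlation adjusted p = 0.00187). By line they were -0.42, -1.26 and -1.03. Of 20 serine, glycine and one-carbon genes, 2 rose, 16 fell and 2 did not pass on average, with log2 fold changes such as PHGDH (-0.87) and MTHFD2 (-0.90). The one-carbon median was -0.93, or -0.97 with low-count members at their bounds (camera adjusted p = 2.55e-08, with an estimated correlation adjusted p = 0.0168). Of 28 RNA polymerase I and III subunit genes, 2 rose, 20 fell and 6 did not pass on average, with log2 fold changes such as POLR3G (-2.47) and POLR1B (-1.01). The polymerase median was -0.45 (camera adjusted p = 1.67e-06, with an estimated correlation adjusted p = 0.0198).

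Of 8 guanylate-binding protein and GIMAP genes, 6 rose and 2 did not pass on average. The GBP and GIMAP median was 2.21, or 1.95 with low-count members at their bounds (camera adjusted p = 0.000245, with an estimated correlation adjusted p = 0.0198). In KMS20 alone that list did not pass (0.0508, with an estimated correlation 0.211). The difference between AMO1 and KMS20 held with an estimated correlation for the quiescence list (0.0131) and the nucleotide list (0.00906). A further 4 lists passed on average with camera and not with an estimated correlation. Of 208 small nucleolar RNA genes 119 fell and 2 rose (median -0.93, or -0.92 with low-count members at their bounds, adjusted p = 0.122 with an estimated correlation); reads shared with host genes were not separated. Of 23 aminoacyl-tRNA synthetase genes 19 fell and 1 rose (median -0.50, 0.0769), of 42 lysosomal genes 26 rose and 2 fell (0.58, or 0.55 with bounds, 0.0769), and of 20 genes of MHC class I presentation 12 rose and 4 fell (0.51, 0.299). In KMS20 alone the class I list did not pass (5 rose, 4 fell, camera adjusted p = 0.815), and it differed there from AMO1 and H929 with camera (3.29e-05 and 0.000107) but not with an estimated correlation (0.152 and 0.299). The MHC class II list did not pass on average (7 of 14 rose, median 0.59, or 0.90 with bounds, camera adjusted p = 0.0650). It passed with camera in AMO1 (8 rose, 0.00171) and H929 (6 rose, 0.0232), and not in KMS20 (4 rose, 0.0758). With an estimated correlation it passed in neither AMO1 nor H929 (0.276 and 0.415).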
